A study of Mus musculus with 8 samples.

How the data were processed

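RNA from mouse embryonic stem cells was measured on 8 Affymetrix whole-genome arrays, 1 per sample, after labelling of cRNA made from 200 ng of RNA. The deposited table holds log2 values, 1 per probe set and array, for 45101 probe sets. The submitters' processing notes name R 2.7.2, and the methods of background correction, normalization and summarization are not given in the sources used here. The unit was read from the values. In 74.5% of the probe sets the 8 values spanned less than 0.01, and 33238 spanned less than 1e-06, so the table holds no measured difference for them. Raw scans and signal over background were not analysed here, and the number of arrays limits the precision.

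Probe sets were joined to genes through the platform's gene table: 34958 had 1 gene symbol, 932 had several and 9211 had none. The last 2 kinds stayed out of the tests. Of the 34958, 34754 had a gene ID in the reference gene table, and 0 symbols had to be updated. Each of the 18194 genes was represented by its probe set with the highest mean over the 8 arrays, of which 11648 were flat, and 635 of those genes had another probe set that was not flat. Groups came from the genotype in the labels. The labels number the replicates of each group, but the deviations of replicates with the same number correlated between -0.12 and 0.22, so the arrays were not paired.

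A linear model with 4 group means was fitted to the 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom), and p-values were adjusted over the 18194 genes by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were each KO group against WT, double-KO against either single KO, and the interaction. Because most genes were flat, the estimated prior had 0.112 degrees of freedom and a variance of 1.68e-19, which leaves each gene's own spread as the error. A second fit, chosen after seeing the data, took the 7181 genes with a probe set spanning at least 0.01, with 1.91 prior degrees of freedom and a prior variance of 0.00676. Flat genes past the threshold are counted in the planned counts and never called higher or lower by name.

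Genes named by rule were the 12 with the largest rise and the 12 with the largest fall per comparison among genes past the threshold whose arrays did not overlap between the groups, 6 each way for the interaction, and Kdm3a and Kdm3b always. Further genes are named as members of gene lists and were picked by eye. The 21 gene lists had 431 members, of which 379 had a gene on the array. They covered H3K9 enzymes and readers, DNA methylation, core and naive pluripotency, the formative epiblast, endoderm, mesoderm, neuroectoderm, trophoblast, the 2-cell-like state, germline genes, X-linked Rhox and Xlr genes, imprinted genes, hypoxia, p53, proliferation, the integrated stress response, cholesterol biosynthesis, interferon, fibroblast markers and Y-linked genes. Each was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over 126 tests. These tests took every member with a gene on the array, flat ones included, and camera set them against all other genes. Counts and medians of list members cover measured genes in the planned fit unless said otherwise. Changes were correlated across genes by Pearson's and Spearman's methods and set beside 100 draws of simulated unchanged groups.

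The scripts were tested on simulated data with 200 changed genes, in 10 runs of double-KO against WT. The planned fit of 18194 genes recovered 20.3% of changes of 0.5, 49.7% of changes of 1 and 79.1% of changes of 2 on the log2 scale, with 4.62% false calls. A fit of the 6546 measured genes alone recovered 51, 82.2 and 96.8%, with 5.2% false calls. It is not the fit of 7181 informative genes, which holds 635 genes more and was not simulated itself. The simulated arrays had the same spread per gene in every group, and genes were independent. In the data the replicates of some groups differed more than those of others, so these rates may not hold there.

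Lists, contrasts, naming rule and most alternatives were fixed before the data were examined. These alternatives were the mean of all probe sets of a gene, every probe set, quantile normalization, centring of arrays on their median, a filter on low means, a robust eBayes with trend, a fit of only the groups compared, a replicate block, array weights, omission of each array, a log2 change of at least 1 and an adjusted p under 0.01. Not counting flat genes, the informative genes, correlations over measured genes, lists without the deleted genes and a block with the double-KO numbers crossed were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.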

Results

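Gene expression was measured in mouse embryonic stem cells with and without the related histone demethylases Jmjd1a and Jmjd1b, enzymes that remove methyl groups from H3K9 and whose genes are now named Kdm3a and Kdm3b. The 8 arrays fell into 4 groups of 2 biological replicates: wild-type cells (WT), cells without Jmjd1a (Jmjd1a-KO), cells without Jmjd1b (Jmjd1b-KO) and cells without both (double-KO). Cells grew with the cytokine LIF, which keeps embryonic stem cells undifferentiated. The double-KO cells came from a Jmjd1a-deficient line that had received a conditional Jmjd1b allele, which the compound OHT deleted through an inducible Cre recombinase. The protocol of all 8 samples names OHT at 800 nM, and no sample is labelled as an OHT control. Which replicate came from which line is not given in the sources used here. The labels describe WT and Jmjd1b-KO as cells from mice and the design as targeted lines, so whether they share the background of the Jmjd1a-deficient line is open, and every change against WT holds any difference between the lines too. The number of arrays limited the precision. Array medians lay between 6.80 and 6.81 on the log2 scale. Replicates of Jmjd1a-KO and double-KO differed more than those of the other groups: the SD of the replicate difference over 7181 genes was 0.34 and 0.29, against 0.15 in WT and 0.12 in Jmjd1b-KO. The mean difference between the Actb probe sets for the ends of the transcript, a sign of RNA quality, lay between 0.53 and 0.57 in the 4 groups. That of Gapdh was -0.08 in WT, -0.09 in Jmjd1a-KO, -0.08 in Jmjd1b-KO and -0.01 in double-KO. The 18S rRNA probe set was less even, with means of 12.1 in WT (SD 0.71), 13.1 in Jmjd1a-KO, 11.9 in Jmjd1b-KO (SD 0.68) and 12.5 in double-KO.

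Of the 45101 probe sets, 33599 (74.5%) had values that spanned less than 0.01 over the 8 arrays, so that they carried no measured difference and are called flat below. After 1 probe set per gene was taken, 11648 of 18194 genes were flat and 6546 were measured. All changes below are log2 differences of group means ± SE from the limma fit over the 8 arrays, with 2 arrays per group. The SE rests on an error shared by all groups, so it does not follow the spread of the groups compared. A gene rose or fell only if it was measured and had an adjusted p under 0.05. Signal over background was not examined. A change from or to a value near or below the lower quartile of an array (6.341 to 6.346) is therefore uncertain in size and rank, whatever its SE.

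The transcripts of the deleted genes were checked first. Kdm3a had a mean of 12.78 in WT and 12.81 in Jmjd1b-KO, and of 4.98 in Jmjd1a-KO and 4.68 in double-KO. Kdm3b had a mean of 9.93 in WT and 9.88 in Jmjd1a-KO, and of 7.08 in Jmjd1b-KO and 7.36 in double-KO. Kdm3a thus fell by 7.81 ± 0.10 in Jmjd1a-KO (adjusted p = 0.000318) and Kdm3b fell by 2.85 ± 0.22 in Jmjd1b-KO (adjusted p = 0.0148). A second Kdm3b probe set was flat at 7.58, and whether either probe set lies in the deleted exons is not given in the sources used here.

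**Figure D1:**
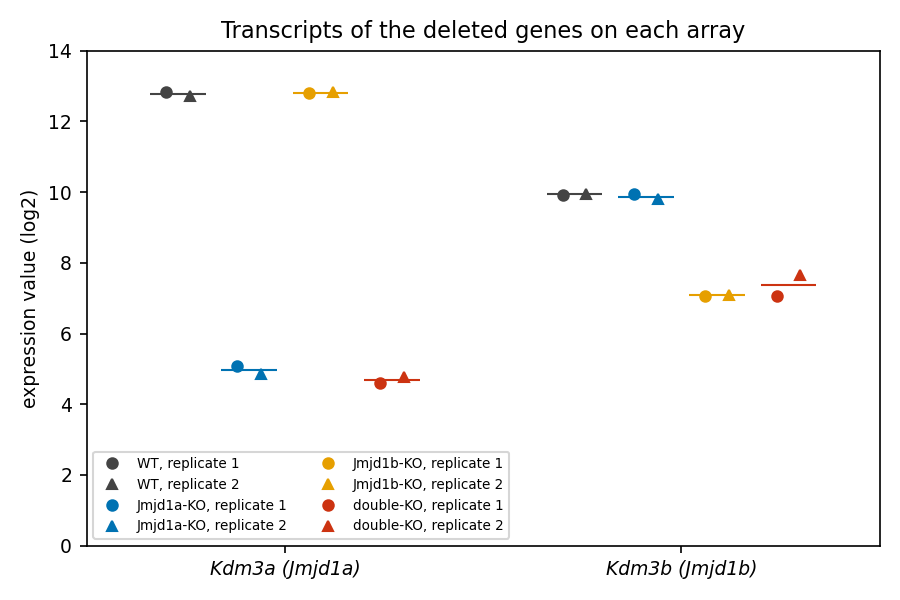
Expression value (log2, y axis) of Kdm3a and Kdm3b on each of the 8 arrays, with circles for replicate 1, triangles for replicate 2, colours for the 4 groups and short lines for group means. The means of Kdm3a were 4.98 and 4.68 in the groups without Jmjd1a, and those of Kdm3b were 7.08 and 7.36 in the groups without Jmjd1b.

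In the planned fit, loss of both demethylases went with more gene changes than loss of either, a ranking that did not hold in all settings. Each gene had a common error over all groups, although the replicates of Jmjd1a-KO and double-KO differed more than the others. This error tends to be too large for Jmjd1b-KO against WT and too small for double-KO against Jmjd1a-KO. Counts of different comparisons therefore do not rank the effects of the losses. Among measured genes, 109 rose and 94 fell in Jmjd1a-KO against WT, 158 rose and 97 fell in Jmjd1b-KO, and 1111 rose and 722 fell in double-KO. Against Jmjd1a-KO, 395 genes rose and 228 fell in double-KO, and against Jmjd1b-KO 1118 rose and 981 fell. The planned counts over all 18194 genes, flat ones included, were 374, 425, 2316, 816 and 2629 in the same order, of which 171, 170, 483, 193 and 530 were flat with changes of at most 0.006. A fit of the 7181 genes with an informative probe set, chosen after seeing the data, gave 1301, 1708, 3477, 2155 and 3721 genes. Jmjd1b-KO had more genes against WT than double-KO with only the groups compared in the fit (1146 against 131, and 3335 against 3228 among informative genes), with array weights (2661 against 2428) and with centred arrays (14138, of which 11645 were flat, against 2159). Among informative genes double-KO had more with array weights (3606 against 3582) and with centring (3481 against 1753).

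Scaling moved the split between higher and lower genes. Quantile normalization took the share of higher genes in the planned counts from 57.6 to 30.2% in double-KO against WT, from 60 to 44.6% against Jmjd1a-KO and from 49.7 to 14.4% against Jmjd1b-KO, while among measured genes it went from 60.6 to 52.2%, from 63.4 to 54.7% and from 53.3 to 50.1%. Centring took the planned share from 61.9 to 93.1% in Jmjd1b-KO against WT and from 49.7 to 12.9% in double-KO against Jmjd1b-KO, and the measured share from 62 to 61% and from 53.3 to 52%. It took the planned share of positive genes in the interaction from 49.4 to 8.86%. The measured majority turned in Jmjd1a-KO against WT, from 53.7% higher to 46.9% with quantile normalization, and in the interaction, from 54.9 to 48.6% with centring.

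**Figure D2:**
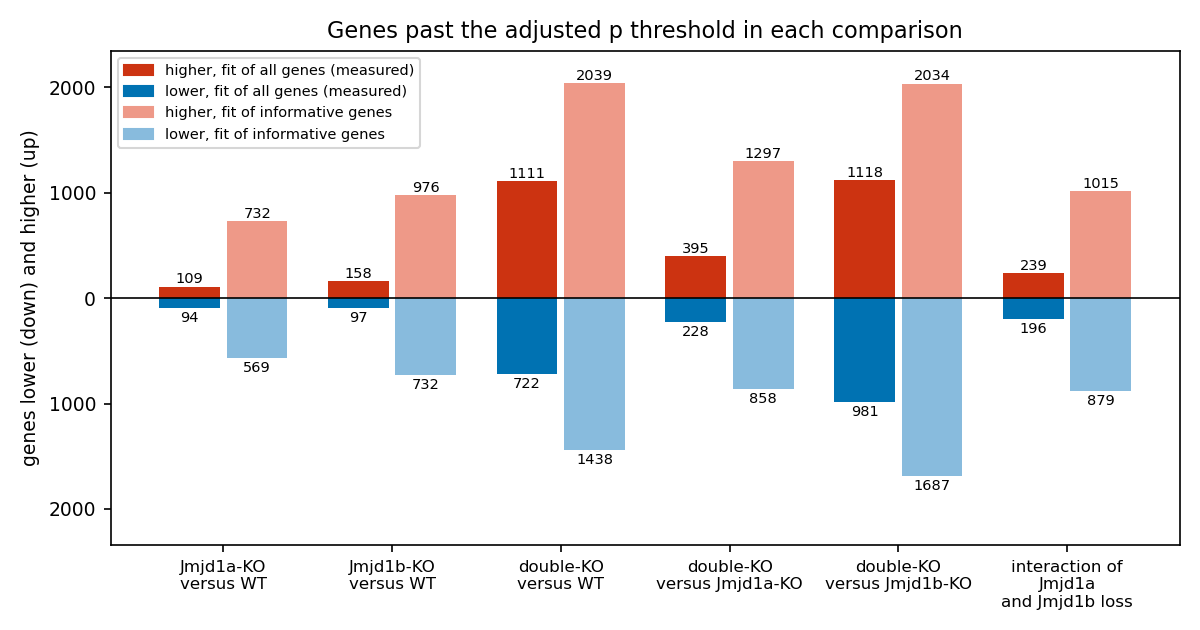
Number of genes (y axis, higher above 0 and lower below 0) past the adjusted p threshold in each comparison, in dark bars for measured genes in the fit of all genes and in light bars for the fit of informative genes. In double-KO against WT, 1111 measured genes were higher and 722 lower, against 109 and 94 in Jmjd1a-KO and 158 and 97 in Jmjd1b-KO.

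Loss of Jmjd1a alone was read from Jmjd1a-KO against WT. The largest falls after Kdm3a itself were of the imprinted noncoding RNAs Rian (-6.71 ± 0.45, adjusted p = 0.00996) and Meg3 (-4.94 ± 0.60, adjusted p = 0.0497). Both RNAs ended below the lower quartile of the Jmjd1a-KO arrays (6.343 and 6.345), so the sizes of these falls are uncertain. Cdkn1c, an imprinted inhibitor of the cell cycle, fell by 3.67 ± 0.32, and Gstp1, a detoxifying enzyme, fell by 2.60 ± 0.03. Tfap2c, a transcription factor of trophoblast and germ cells, rose by 2.48 ± 0.12. The imprinted genes Impact and Peg3 rose by 1.52 and 1.39. Cd200, a surface glycoprotein, rose by 1.83, and Mme, a membrane peptidase, by 1.84. Also higher were Nlrp4f, Diaph2, Ccdc85a, Coch, Stk26, Slc40a1 and Runx1t1, by 1.24 to 1.69, and lower were Plac8, AI662270, Ak7, Tgfbi, Myl9, Fam111a and Ly6e, by -2.80 to -1.99. Nlrp4f and Gstp1 belong to families of similar genes, so which copy was measured is uncertain.

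Of 16 measured germline genes that promoter methylation silences, 0 rose and 2 fell in Jmjd1a-KO, Sohlh2 (-1.82) and Hormad1 (-1.40), with 6 lower when adjusted over the list alone. The list had a median of -0.48 (adjusted p = 1.51e-05 by camera, and adjusted p = 0.32 with an estimated correlation). Of 13 measured fibroblast markers, Col1a2 (-1.71) fell, 6 were lower when adjusted over the list alone, and the median was -0.74 (adjusted p = 0.000382, and adjusted p = 0.32 with an estimated correlation). Of 14 genes of the p53 response, Perp (1.05), Zmat3 (0.75) and Ccng1 (0.73) rose, 5 were higher when adjusted over the list alone, and the median was 0.36 (adjusted p = 0.00468, and adjusted p = 0.32 with an estimated correlation). No cholesterol biosynthesis gene passed over all genes, yet 5 of 15 did when adjusted over the list alone, Cyp51 (0.97) and Insig1 (0.92) among them. The list median was 0.27 (adjusted p = 0.00318, and adjusted p = 0.614 with an estimated correlation). Of 6 interferon response genes, Oasl2 (-1.14) and Irf1 (-0.79) fell, 3 were lower when adjusted over the list alone, and the median was -0.52 (adjusted p = 0.0372, and adjusted p = 0.415 with an estimated correlation). The integrated stress response list had a median of -0.30 with 0 of 19 genes past the threshold and 1 lower when adjusted over the list alone (adjusted p = 0.0118, and adjusted p = 0.656 with an estimated correlation). The hypoxia and glycolysis list had a median of 0.37 with 0 of 23 past the threshold, over all genes or adjusted over the list alone (adjusted p = 0.0387, and adjusted p = 0.874 with an estimated correlation). The p53 and hypoxia calls were lost under quantile normalization (adjusted p = 0.412 and 0.0982) and with centring (adjusted p = 0.132 and 0.485). By fry the cholesterol, stress response and hypoxia lists had no call (adjusted p = 0.129, 0.208 and 0.493).

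The count of 374 for Jmjd1a-KO against WT was 17 without WT replicate 1, 16 without WT replicate 2 and 982 without Jmjd1a-KO replicate 2. Of the 24 genes named by rule, Kdm3a and Gstp1 kept their call without each array in turn, and all 24 did so among informative genes. Without Jmjd1a-KO replicate 1 the hypoxia list had an adjusted p of 0.952, without Jmjd1a-KO replicate 2 the stress response list 0.118, and without WT replicate 2 the interferon list 0.127. The interferon call was also lost without Jmjd1a-KO replicates 1 and 2 (0.135 and 0.0939) and Jmjd1b-KO replicates 1 and 2 (0.0586 and 0.0541). The hypoxia call was lost without WT replicates 1 and 2 (0.126 and 0.122), Jmjd1b-KO replicates 1 and 2 (0.071 and 0.0654) and double-KO replicates 1 and 2 (0.0591 and 0.0545).

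Loss of Jmjd1b alone was read from Jmjd1b-KO against WT. Fos, an immediate early transcription factor, rose by 6.13 ± 0.30 (adjusted p = 0.0102), and the X-linked homeobox gene Rhox5 rose by 3.30 ± 0.18 (adjusted p = 0.0102). Hormad1, a protein of meiotic chromosomes, rose by 1.90, the keratin Krt19 by 1.78, and Cth, an enzyme of cysteine synthesis, by 2.25. Among the largest falls, Acta2 fell by 4.75 ± 0.48 (adjusted p = 0.0322), Col1a2 fell by 3.74 ± 0.18, Tagln fell by 3.32 ± 0.28 and Col3a1 fell by 2.88 ± 0.20. Tgfbi, Cdkn1c, Col5a2, Actc1, Nrep, Ccnd2 and Dpysl2 fell too, by -3.71 to -2.24. G730013B05Rik, Fermt3, Abcd4, Notch4, AU018091, Slc44a2 and Klhl10 rose by 1.43 to 1.72.

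The fibroblast markers made up the list with the lowest median in Jmjd1b-KO against WT, at -1.64: of 13 measured members 7 fell and Thy1 (0.56) rose, and 10 were lower when adjusted over the list alone (adjusted p = 2.65e-06, and adjusted p = 0.32 with an estimated correlation). Of 16 germline genes 5 rose, with Hormad1, Stk31 (1.38), Sycp3 (1.37) and Dazl (1.32) among them, and 9 when adjusted over the list alone. Their median was 0.77 (adjusted p = 4e-04, and adjusted p = 0.32 with an estimated correlation). Of 9 trophoblast genes, Krt19, Tfap2c (1.40) and Krt18 (0.97) rose, 5 were higher when adjusted over the list alone, and the median was 0.78 (adjusted p = 0.0014, and adjusted p = 0.32 with an estimated correlation). Of 23 hypoxia and glycolysis genes P4ha2 (0.91) rose, 1 was higher when adjusted over the list alone, and the median was 0.91 (adjusted p = 0.000123, and adjusted p = 0.641 with an estimated correlation). In the fit of informative genes 6 of these 23 were higher, and 12 when adjusted over the list alone. No neuroectoderm gene passed over all genes, and Fabp7 (-5.40) did when adjusted over the list alone. The median of the 11 was -0.89 (adjusted p = 0.000687, and adjusted p = 0.443 with an estimated correlation). In the fit of informative genes 6 of 12 neuroectoderm genes were lower, and 7 when adjusted over the list alone. The fry test gave no call for this list (adjusted p = 0.0627). Of 21 imprinted genes Cdkn1c, Igf2 (-0.98) and Gnas (-0.93) fell and Peg3 (0.90) rose, 5 were lower and 1 higher when adjusted over the list alone, and the median was -0.56 (adjusted p = 0.0302, and adjusted p = 0.439 with an estimated correlation). The stress response list had a median of 0.34 with 0 of 19 past the threshold, over all genes or adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.696 with an estimated correlation). With centred arrays, the adjusted p was 0.547 for hypoxia, 0.717 for the stress response, 0.0849 for germline genes and 0.0697 for trophoblast genes. Quantile normalization also lost the hypoxia and stress response calls (adjusted p = 0.0745 and 0.389).

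The count of 425 for Jmjd1b-KO against WT was 6 without WT replicate 1, 9 without WT replicate 2, 9 without Jmjd1b-KO replicate 1, 11 without Jmjd1b-KO replicate 2 and 697 without either Jmjd1a-KO array. None of the 24 named genes kept its planned call without each array in turn, against 19 among informative genes, where Cth, Krt19, G730013B05Rik, Notch4 and Slc44a2 lost theirs. The imprinted call was lost without WT replicate 1 (0.0719), Jmjd1b-KO replicate 2 (0.0735) and double-KO replicates 1 and 2 (0.0609 and 0.0594), and the stress response call without WT replicate 1 (0.0755) and Jmjd1b-KO replicate 2 (0.0982).

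Loss of both demethylases was read from double-KO against WT. Usp17la, a deubiquitinase gene of a family of similar copies, rose by 4.48 ± 0.04 (adjusted p = 6.89e-05), and Tfap2c rose by 3.89 ± 0.12 (adjusted p = 0.00287). Kitl, the ligand of the Kit receptor, rose by 3.39 ± 0.33, Dsp, a desmosome protein, by 3.65 and Gbp2, an interferon-inducible GTPase, by 3.19. Among the falls were Rian (-6.52), Grb10 (-5.75), Phlda2 (-5.05), Meg3 (-5.01) and Cdkn1c (-3.95), members of the imprinted list, which as a whole had no call (adjusted p = 0.971). Their sizes depended on the probe sets used: with the mean of all probe sets of the gene, Rian had -3.62, Grb10 -1.92 and Meg3 -2.29. Where a gene has flat probe sets, this mean takes them in, which draws a change toward 0 by construction. The probe sets of Rian were all informative and had changes from -6.52 to -1.38. Plac8 fell by 6.06 ± 0.24, Stra8, a gene induced by retinoic acid before meiosis, fell by 4.78 ± 0.42, and Ccnd1, which encodes a cyclin of the early cell cycle, fell by 4.03 ± 0.35. Cox7b2, Vwa5a, Rnf128, Cd200, C130073F10Rik, Ndrg1 and AU015836 rose by 3.11 to 4.23, and Pcolce, Ak7 and Mymx fell, by -5.72 to -4.48.

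Genes of the integrated stress response, which raises amino acid supply under stress, were lower in double-KO than in WT: 10 of 19 fell, 15 when adjusted over the list alone, with Chac1 (-3.25), Mthfd2 (-2.83), Psat1 (-2.15) and the regulator Atf4 (-1.35) among them. The median was -1.09 (adjusted p = 2.85e-08, and adjusted p = 0.43 with an estimated correlation). Of 15 cholesterol biosynthesis genes 4 fell, with Lss (-1.50) and Sc5d (-1.20) the lowest, Cyp51 (0.96) rose, and 11 were lower and 3 higher when adjusted over the list alone. The median was -0.71 (adjusted p = 0.00398, and adjusted p = 0.614 with an estimated correlation). Of the 19 listed genes of the 2-cell-like state 10 had a gene on the array, and the Zscan4 genes and Dux had no probe set of their own. All 3 measured genes of this list rose, over all genes and adjusted over the list alone: Usp17la, Tcstv1 (1.68) and Arg2 (0.59). Their median was 1.68. The list test, which also took in 7 flat members, gave adjusted p = 0.0302, and adjusted p = 0.415 with an estimated correlation. With so few listed genes measured, these values do not show that cells were in such a state. Among 11 genes of DNA methylation, the methyltransferase Dnmt3a (-3.32) and its cofactor Dnmt3l (-2.10) fell, Uhrf2 (0.30) rose, and 4 were lower and 1 higher when adjusted over the list alone. The median was -0.52 (adjusted p = 0.0372, and adjusted p = 0.518 with an estimated correlation). Of 11 measured H3K9 enzymes and readers, the deleted Kdm3a and Kdm3b fell and no other passed, over all genes or adjusted over the list alone (median -0.26, adjusted p = 0.00685, and adjusted p = 0.32 with an estimated correlation). Without these 2 genes, whose falls follow from the genotype, the call was lost (median -0.18, adjusted p = 0.0537). In the fit of informative genes, however, 6 of the 11 members were lower and 1 higher, over all genes and adjusted over the list alone.

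Pou5f1, the central pluripotency factor, had a mean of 12.32 in double-KO against 12.45 in WT (change -0.13, not past the threshold). Of 18 core genes, Nanog (1.34), Zfp42 (1.33) and Sox2 (0.67) rose and L1td1 (-0.27) fell, with 5 higher and 2 lower when adjusted over the list alone and an adjusted p of 0.687 for the list. Of 17 naive genes Klf2 (1.97) and Dppa3 (0.76) rose (list adjusted p = 0.687), and of 17 formative genes Dnmt3a fell (list adjusted p = 0.434). Germline genes split, with 8 of 16 higher, Dazl (2.85), Slc25a31 (2.06) and Mael (1.86) first, and Stra8 and Sohlh2 (-1.60) lower. The list test gave an adjusted p of 0.249, and 8 were higher and 4 lower when adjusted over the list alone. Of 9 trophoblast genes 5 rose, Tfap2c and Krt8 (2.40) first (list adjusted p = 0.259), and of 21 imprinted genes 6 rose and 5 fell (list adjusted p = 0.971). Of 12 endoderm genes 3 rose and 1 fell (list adjusted p = 0.0613), of 23 hypoxia genes 3 rose (list adjusted p = 0.0646), and of 13 fibroblast markers 4 fell (list adjusted p = 0.105). Of 17 proliferation genes Cdk1 (0.57) and Plk1 (0.18) rose, and 4 fell, Ccne1 (-1.50) and Rrm2 (-1.22) first (list adjusted p = 0.601). Irf1 (2.82) and Oasl2 (1.10) rose and Oas1a (-0.99) fell among 6 interferon response genes (list adjusted p = 0.725). These list values are from camera. By fry the interferon, trophoblast, germline and endoderm lists were called higher (adjusted p = 0.00137, 0.0113, 0.0198 and 0.0318). The fibroblast and Rhox lists were called lower by fry (adjusted p = 0.0154 and 0.0198).

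The count of 2316 for double-KO against WT was 753 without WT replicate 1, 836 without WT replicate 2, 986 without either Jmjd1b-KO array, 1120 without double-KO replicate 1 and 1310 without double-KO replicate 2. Of 24 named genes 11 kept their planned call without each array in turn, and all 24 did so among informative genes. The 2-cell-like call was lost without WT replicate 1 (0.0815), and the DNA methylation call without WT replicate 1 (0.131), double-KO replicate 1 (0.0609), Jmjd1b-KO replicates 1 and 2 (0.0608 and 0.056) and under quantile normalization (0.101). Of the 1833 measured genes called, 180 were also called in Jmjd1a-KO and 160 in Jmjd1b-KO against WT, 51 of them in both, and 1544 in neither, of which 190 passed the test of the interaction. The direction was opposite for 7 of the 180 and for 42 of the 160. Of the 3477 genes called in the fit of informative genes, 1042 were also called in Jmjd1a-KO and 1027 in Jmjd1b-KO. These included 422 called in both, and 1830 were called in neither. The direction was opposite for 43 of the 1042 and for 348 of the 1027. A gene without a call in a single loss is not thereby unchanged in it.

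**Figure D3:**
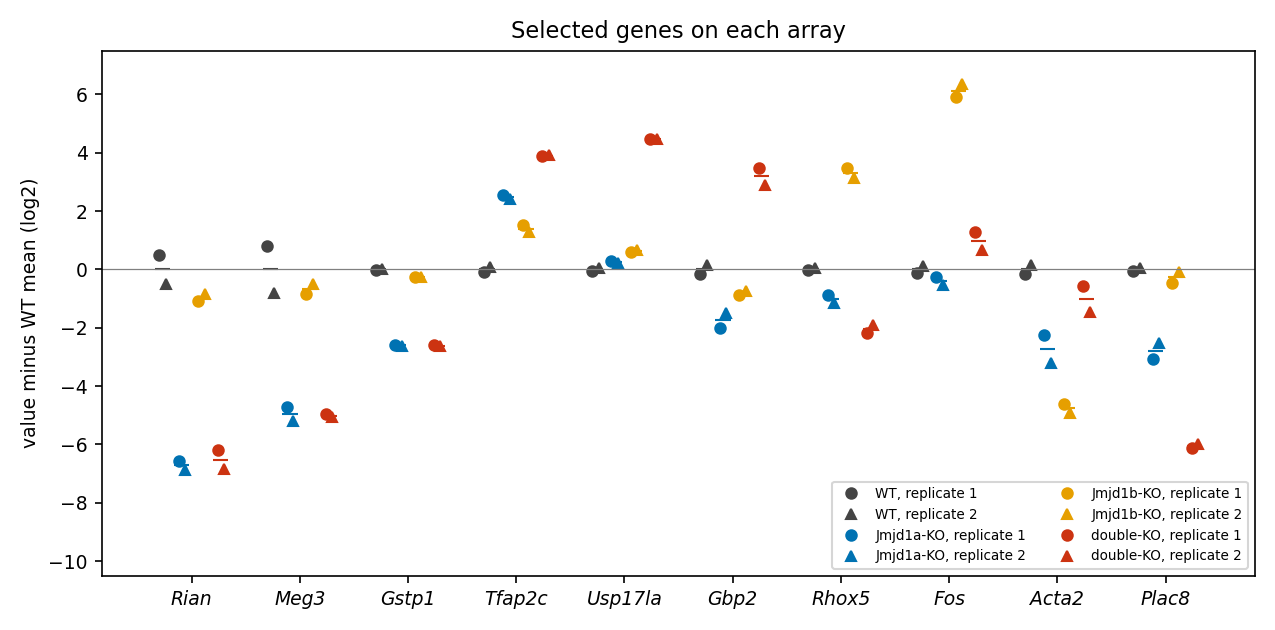
Value minus the WT mean (log2, y axis) of 10 genes on each of the 8 arrays, with circles for replicate 1, triangles for replicate 2, colours for the groups and short lines for group means. Rian and Meg3 lay low in both groups without Jmjd1a (mean changes -6.71 and -6.52 for Rian), Usp17la lay high in double-KO (4.48), and Fos and Rhox5 lay high in Jmjd1b-KO (6.13 and 3.30).

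Deletion of Jmjd1b in cells that already lacked Jmjd1a was read from double-KO against Jmjd1a-KO, the line from which the double-KO cells came. Gbp2 rose by 4.93 ± 0.29 (adjusted p = 0.00857), the transcription factor Irf1 by 3.61 ± 0.05 (adjusted p = 0.000818) and Irgm1 by 3.08 ± 0.42. Of 6 measured interferon response genes 2 rose, over all genes and adjusted over the list alone. The list had no call by camera (adjusted p = 0.291, and adjusted p = 0.587 with an estimated correlation), but it was called higher by fry (adjusted p = 0.000843). Usp17la rose by 4.22 ± 0.04, the germ cell RNA-binding gene Dazl by 2.78 ± 0.07 and the germ cell gene Tex19.1 by 3.25 ± 0.23. Pcolce, which helps to process collagen, fell by 4.60 ± 0.35, Phlda2 fell by 2.95 ± 0.28, Neurod1, a neuronal transcription factor, fell by 2.91 ± 0.42, and Ccnd1 fell by 2.77 ± 0.35. Kdm3b fell by 2.52 ± 0.22. Rpl39l, Nmi, Cox7b2, Vwa5a, Ptpn13 and Trim12c, the last from a family of similar genes, rose by 2.74 to 3.42, and Plac8, Bcat1, Plekha4, Ifitm3, Mthfd2, Eprn and Ddc fell, by -3.26 to -2.26.

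Of 16 germline genes 7 rose in double-KO against Jmjd1a-KO, with Dazl, Slc25a31 (2.53), Mael (2.49) and Stk31 (1.70) first, and 12 were higher and 1 lower when adjusted over the list alone. The median was 0.92 (adjusted p = 8.37e-07, and adjusted p = 0.32 with an estimated correlation). Of 15 cholesterol biosynthesis genes 5 fell, 12 when adjusted over the list alone, with Msmo1 (-1.88), Lss (-1.86) and Sc5d (-1.10) first, and the median was -0.92 (adjusted p = 1.81e-07, and adjusted p = 0.43 with an estimated correlation). Of 19 stress response genes Mthfd2 and Psat1 (-1.42) fell, 10 when adjusted over the list alone, and the median was -0.73 (adjusted p = 9.67e-08, and adjusted p = 0.43 with an estimated correlation). Of 3 genes of the 2-cell-like state Usp17la and Tcstv1 (1.53) rose, all 3 when adjusted over the list alone, and the median was 1.53 (adjusted p = 0.0101, and adjusted p = 0.39 with an estimated correlation). Meg3 and Rian had values of -0.07 and 0.19, not past the threshold. Among fibroblast markers Cald1 (1.29) rose and Col1a1 (-1.27) and Col1a2 (-1.26) fell.

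The count of 816 for double-KO against Jmjd1a-KO was 487 without either WT array and 421 without either Jmjd1b-KO array. Of 24 named genes 7 kept their planned call without each array in turn, and all 24 did so among informative genes.

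The effect of Jmjd1a loss in cells without Jmjd1b was read from double-KO against Jmjd1b-KO, which were made in separate ways. Plagl1, an imprinted zinc finger gene, rose by 4.35 ± 0.60 (adjusted p = 0.0227), and Id4, an inhibitor of differentiation factors, rose by 4.11 ± 0.65. Kitl rose by 3.71 ± 0.33, Acta2 by 3.75 ± 0.48 and Gbp2 by 3.99 ± 0.29. After Kdm3a (-8.13), the largest falls were of Plac8 (-5.79 ± 0.24), Rian (-5.56 ± 0.45), Rhox5 (-5.35 ± 0.18), Fos (-5.16 ± 0.30), the stress gene Nupr1 (-5.16 ± 0.40) and Phlda2 (-5.05 ± 0.28). Frmd4b, Usp17la, Ptn, Lpar6, Nrk, Dcaf12l1 and Tox3 rose by 3.39 to 4.18, and Plekha4, Pcolce, Stra8, Meg3 and Ak7 fell, by -4.77 to -4.00.

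Of 19 stress response genes 16 fell in double-KO against Jmjd1b-KO, 18 when adjusted over the list alone, and the median was -1.27 (adjusted p = 3.64e-09, and adjusted p = 0.425 with an estimated correlation). Of 15 cholesterol biosynthesis genes 9 fell, Lss (-2.36) first, Insig1 (1.24) rose, and 11 were lower and 2 higher when adjusted over the list alone. The median was -0.93 (adjusted p = 0.00197, and adjusted p = 0.614 with an estimated correlation). Of 12 endoderm genes 6 rose, the basement membrane genes Col4a1 (2.52) and Lama1 (1.93) first, Amn (-0.98) fell, and 8 were higher and 1 lower when adjusted over the list alone. The median was 1.12 (adjusted p = 0.00619, and adjusted p = 0.415 with an estimated correlation). Of 13 fibroblast markers 5 rose, Acta2, Col3a1 (3.05) and Tagln (3.01) first, Thy1 (-1.05) fell, and 8 were higher and 1 lower when adjusted over the list alone. The median was 0.81 (adjusted p = 0.0248, and adjusted p = 0.415 with an estimated correlation). Usp17la and Tcstv1 (1.39) rose among 3 genes of the 2-cell-like state, all 3 when adjusted over the list alone (median 1.39, adjusted p = 0.0335, and adjusted p = 0.415 with an estimated correlation). Among the 3 measured X-linked Rhox genes Rhox5 fell, 2 when adjusted over the list alone (median -1.48, adjusted p = 0.0295, and adjusted p = 0.443 with an estimated correlation). Under quantile normalization the adjusted p was 0.35 for cholesterol biosynthesis, 0.145 for the 2-cell-like state and 0.213 for the Rhox genes.

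The count of 2629 for double-KO against Jmjd1b-KO was 1425 without either WT array, 802 without Jmjd1b-KO replicate 1, 720 without Jmjd1b-KO replicate 2, 1152 without double-KO replicate 1 and 1688 without double-KO replicate 2. Of 24 named genes 11 kept their planned call without each array in turn, and all 24 did so among informative genes. The fibroblast call was lost without Jmjd1b-KO replicate 2 (0.0615), the Rhox call without Jmjd1b-KO replicate 1 (0.0512) and double-KO replicate 2 (0.0718), and the 2-cell-like call without Jmjd1a-KO replicates 1 and 2 (0.0601 and 0.0561) and double-KO replicate 2 (0.0545).

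Whether loss of both enzymes differed from the sum of the single losses was tested as an interaction, the change from Jmjd1a-KO to double-KO minus that from WT to Jmjd1b-KO. Any other difference between the WT and Jmjd1b-KO lines enters this value. The double-KO and Jmjd1b-KO cells were also made in separate ways, so neither can be told apart from a dependence on Jmjd1a. For 239 measured genes the interaction was positive and for 196 negative. The largest positive values were of Acta2 (6.49 ± 0.68, adjusted p = 0.0259), which fell in Jmjd1b-KO and had a mean of 11.09 in double-KO against 12.10 in WT, of Gbp2 (5.73 ± 0.41, adjusted p = 0.0204) and of Tagln (4.76 ± 0.40). Anxa1, Rpl39l and Col3a1 had values of 4.72, 3.81 and 3.79. The largest negative values were of Fos (-4.76 ± 0.42, adjusted p = 0.0204) and Rhox5 (-4.33 ± 0.26, adjusted p = 0.0164), both higher in Jmjd1b-KO than in the other groups. Plekha4, Nupr1, Pcolce and Eprn had values of -4.32, -4.10, -3.56 and -3.15.

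For the stress response the interaction was negative: 1 of 19 genes passed, Nupr1, 15 were lower when adjusted over the list alone, and the median was -1.15 (adjusted p = 1.17e-07, and adjusted p = 0.43 with an estimated correlation). Cholesterol biosynthesis had 3 of 15 lower, Lss (-2.71), Sc5d (-1.17) and Idi1 (-0.60), 12 when adjusted over the list alone, and a median of -1.05 (adjusted p = 1.47e-06, and adjusted p = 0.443 with an estimated correlation). Fibroblast markers had 5 of 13 higher and 1 lower, 8 and 1 when adjusted over the list alone, and a median of 1.87 (adjusted p = 0.000177, and adjusted p = 0.32 with an estimated correlation). Weaker list calls were made for the endoderm, 2-cell-like, germline, Rhox, hypoxia and p53 lists, with adjusted p = 0.026, 0.026, 0.0372, 0.0302, 0.0302 and 0.0372 and, in the same order, adjusted p = 0.43, 0.415, 0.43, 0.443, 0.874 and 0.415 with an estimated correlation. When adjusted over the list alone, these 6 had 4, 2, 7, 0, 0 and 0 genes higher and 1, 0, 2, 1, 0 and 2 lower. The planned count of 696, of which 261 were flat, was 137 without WT replicate 1, 41 without WT replicate 2, 1168 without Jmjd1a-KO replicate 2, 19 without Jmjd1b-KO replicate 1, 39 without Jmjd1b-KO replicate 2 and 183 without double-KO replicate 1. It was 1894 among informative genes, where all 12 named genes kept their call without each array in turn, against 0 in the planned fit.

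**Figure D4:**
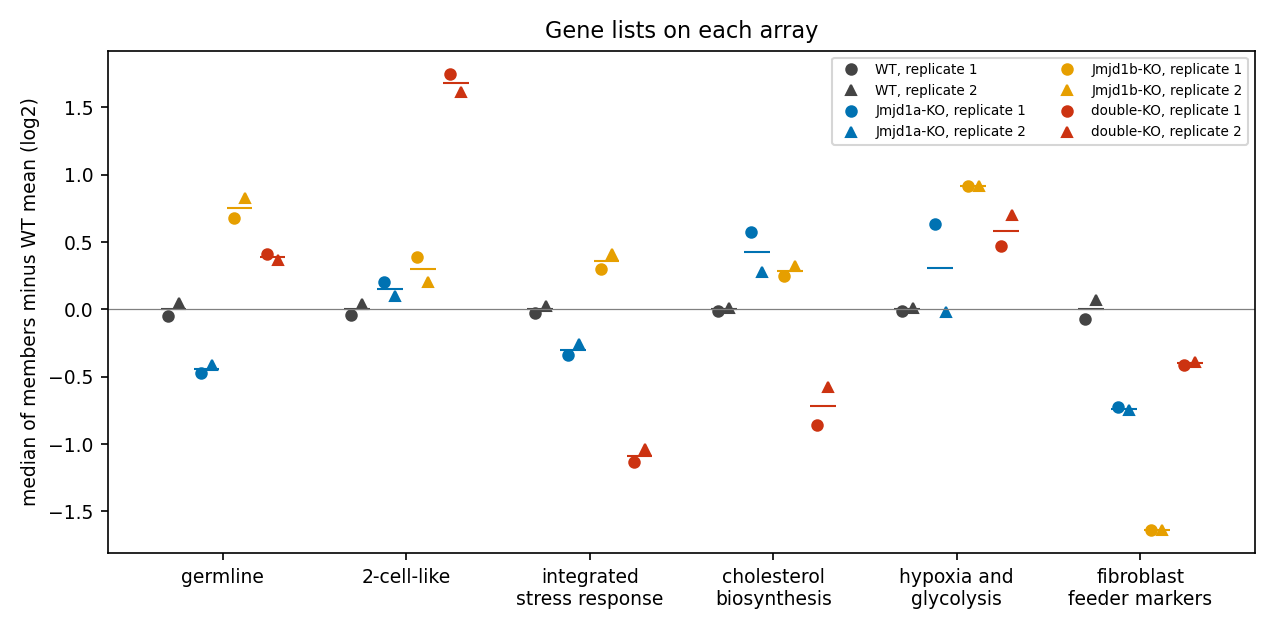
Median over the measured members of 6 gene lists of the value minus the WT mean (log2, y axis) on each of the 8 arrays, with circles for replicate 1, triangles for replicate 2, colours for the groups and short lines for group means. Stress response and cholesterol genes lay lowest in double-KO (median changes -1.09 and -0.71 against WT), and fibroblast markers lay lowest in Jmjd1b-KO (-1.64).

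The effect of losing Jmjd1a was compared across genes between cells with and without Jmjd1b, in comparisons that share no array. Both set cells of the 1 Jmjd1a-deficient origin against separately made cells, so a difference between lines would raise this correlation and the shared calls too, which the simulated groups leave out of account. Over the 6546 measured genes the changes had a Pearson r of 0.432 and a Spearman rho of 0.361, and over all 18194 genes, most of them flat, 0.432 and 0.247. In simulated unchanged groups the mean r was 0.0035 and the highest of 100 draws 0.25. Both comparisons called 75 genes higher and 59 lower, against 18.6 and 14.1 by chance among measured genes, and 20 in opposite directions against 32.4 by chance. In the fit of informative genes these were 471 and 339 against 207 and 134 by chance, and 132 opposite. The chance counts take the calls as independent. Both comparisons use the same error for a gene, though, so genes with a small spread tend to pass in both. Rian, Meg3, Plac8, Ak7 and Kdm3a were among the genes lower in both.

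The effect of losing Jmjd1b without and with Jmjd1a had r = 0.0336 and rho = 0.00313 over measured genes, and r = 0.0368 over all genes, where simulated unchanged groups gave a mean of -0.015 and at most 0.21. Both comparisons called 51 genes higher and 9 lower, against 9.53 and 3.38 by chance among measured genes, and 33 in opposite directions against 11.4. In the fit of informative genes, 250 were higher and 105 lower in both, against 176 and 87.5 by chance, and 324 went in opposite directions. Among measured genes, shared calls in the same and in opposite directions both lay above chance, so such an excess alone does not show agreement. Over all genes r was -0.115 without Jmjd1a-KO replicate 2, 0.182 without Jmjd1a-KO replicate 1, -0.0543 without double-KO replicate 2 and 0.142 without double-KO replicate 1. Comparisons that share the WT arrays had r = 0.327 for Jmjd1a-KO and Jmjd1b-KO, 0.686 for Jmjd1a-KO and double-KO and 0.233 for Jmjd1b-KO and double-KO. Simulated unchanged groups gave a mean of 0.5, 0.5 and 0.49. A shared WT gives unchanged groups such an r by construction, so a lower r does not show less agreement than no change would. The covariances were 0.0263, 0.081 and 0.0298, against simulated means of 0.0057, 0.0057 and 0.0055 in the same order. A difference between the WT line and the others would raise them too. Genes are not independent replicates, so no p is given.

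Across all 6 contrasts, 38 of 126 list tests passed with the preset correlation of 0.01 and 0 with an estimated correlation. Before adjustment, 14 of the 126 tests had a p under 0.05 with the estimated correlation. The loss of calls did not need a high correlation. Fibroblast markers had an estimate of 0.00689, below the preset 0.01, while other lists had higher ones, up to 0.657 for hypoxia. Yet the adjusted p of fibroblast markers in Jmjd1b-KO against WT went from 2.65e-06 to 0.32, with p then taken from 4 residual degrees of freedom. The directional test fry, which does not compare a list with other genes, passed 49, of which 30 were also called by camera in the same direction. In the fit of informative genes, which leaves flat members out, camera passed 36 with the preset correlation and 0 with an estimated one. Mesoderm genes, of which Eomes and Bmp4 were measured, had no call. Eomes rose in double-KO against WT (1.16), and Bmp4 fell in double-KO against Jmjd1b-KO (-1.78). The Y-linked list, with 2 measured genes, had no call and no gene past the threshold. The median of the 2 was -0.82 in Jmjd1a-KO, 1.93 in Jmjd1b-KO and -0.42 in double-KO against WT. In double-KO it was 0.40 against Jmjd1a-KO and -2.35 against Jmjd1b-KO, so the missing calls do not show that these genes were unchanged.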

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

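Of the tests in this part, those of the feeder fibroblasts, of 1 atypical culture and of culture differences were chosen only after the result was seen, while the comparison with matched random lists was set before. The results below were picked because they passed the interaction test or come from probe sets outside the comparisons. That test sets the change from Jmjd1a-KO to double-KO against that from WT to Jmjd1b-KO. A line difference between WT and Jmjd1b-KO, or the separate ways of deletion, would enter it too.

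The interaction passed for 435 measured genes. Positive values were 6.49 for Acta2, 5.73 for Gbp2, 4.76 for Tagln, 4.72 for Anxa1, 3.81 for Rpl39l and 3.79 for Col3a1. Negative values were -4.76 for Fos, -4.33 for Rhox5, -4.32 for Plekha4, -4.10 for Nupr1, -3.56 for Pcolce and -3.15 for Eprn. Among gene lists the median interaction was 1.87 for fibroblast markers, 1.23 for the 2-cell-like state, 0.76 for endoderm and 0.33 for germline genes. It was -0.35 for the p53 response, -0.72 for hypoxia and glycolysis, -1.05 for cholesterol biosynthesis, -1.15 for the integrated stress response and -1.30 for X-linked Rhox genes. Without 1 array, the planned count of 696 lay between 19 (without Jmjd1b-KO replicate 1) and 1168 (without Jmjd1a-KO replicate 2), and it was 41 and 137 without WT replicates 2 and 1, 39 without Jmjd1b-KO replicate 2 and 183 without double-KO replicate 1. None of the list calls held with an estimated correlation.

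The camera calls of the fibroblast, stress response and cholesterol lists for the interaction held without each array, but that of cholesterol was lost with centring (adjusted p = 0.0595). Quantile normalization and centring also lost those of the 2-cell-like state (0.162 and 0.137), Rhox genes (0.242 and 0.372), hypoxia (0.786 and 0.502) and p53 (0.924 and 0.926). Among informative genes the germline and p53 calls were lost (0.107 for both), as they were with low means left out, and by fry those of endoderm (0.0913) and hypoxia (0.345). The endoderm call was lost without Jmjd1a-KO replicate 2 (adjusted p = 0.124), Jmjd1b-KO replicate 1 (0.0743) and double-KO replicate 1 (0.0609), and that of the 2-cell-like state without Jmjd1a-KO replicates 1 (0.127) and 2 (0.0561). The germline call was lost without WT replicate 2 (0.104), Jmjd1a-KO replicate 1 (0.0716), Jmjd1b-KO replicate 1 (0.0978), double-KO replicate 1 (0.0987) and double-KO replicate 2 (0.117). For Rhox genes this happened without WT replicate 1 (0.074), Jmjd1a-KO replicate 1 (0.0787), Jmjd1b-KO replicate 1 (0.0581) and double-KO replicate 2 (0.0871). For hypoxia it happened without WT replicates 1 (0.0719) and 2 (0.0722), Jmjd1a-KO replicate 1 (0.218), Jmjd1b-KO replicates 1 (0.0752) and 2 (0.0541) and double-KO replicate 1 (0.0987). For p53 it happened without WT replicate 1 (0.074), Jmjd1b-KO replicates 1 (0.0608) and 2 (0.0541) and double-KO replicates 1 (0.0946) and 2 (0.0622).

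Probe sets without a single gene name were not part of the comparisons, and of 1078 informative ones 61 were higher and 28 lower in double-KO than in WT by at least 1 on the log2 scale past the limma threshold, out of 203 higher and 173 lower in all.

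Of 13 measured fibroblast markers 7 fell and 1 rose in Jmjd1b-KO, with Acta2 going from 12.10 to 7.34, Col1a2 from 10.60 to 6.86 and a list median of -1.64 (adjusted p = 0.32 with an estimated correlation). A candidate explanation is fewer feeder fibroblasts in the Jmjd1b-KO cultures, but 9 of 21 members, Lum and Dcn among them, were flat or rose, and flat values measure nothing, so this cannot be told apart from an effect of the deletion. A different share of feeder fibroblasts in the double-KO than in the Jmjd1a-KO cultures would move all markers one way if they came from feeders alone. Here 3 informative members fell and 5 rose. For that pair this argues against such a share as the only cause, but cannot exclude it beside changes within the stem cells. Whether feeder cells were used, and how many of these genes the stem cells express themselves, is not given in the sources used here. A change within the stem cells stays open and was not tested.

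In double-KO against Jmjd1a-KO, 2 of 19 stress response and 5 of 15 cholesterol genes fell, with a median of -0.88 over the 34 (adjusted p = 0.43 with an estimated correlation for each list). A shift that depends on signal level was tested with 10000 random lists matched on mean signal, whose lowest median was -0.21: the share as low was 1e-04, the smallest the draws can give, which argues against it. A single atypical double-KO culture is argued against by medians of -0.99 and -0.72 with replicates 1 and 2 alone. Cultures that differed in medium age, density or OHT stay open, since the median over these genes of the difference between the 2 double-KO arrays was 0.36, and such a difference between groups cannot be told apart from the effect of losing Jmjd1b with 2 arrays per group.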

How the results depend on the processing

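Of the settings below, not counting flat genes, the informative genes, lists without the deleted genes and the crossed double-KO numbers were chosen only after the data were seen, and the others were fixed before the data were examined. No call of a named gene or a list reversed its direction past the threshold, but splits of counts did. With quantile normalization, measured genes in Jmjd1a-KO against WT went from 109 higher and 94 lower to 106 and 120, and the planned split in double-KO against WT from 1334 and 982 to 1413 and 3263, of which 1973 were flat, with measured genes still mostly higher (1412 against 1291). With centring, the measured interaction went from 239 positive and 196 negative to 1261 and 1331. In the planned fit Jmjd1b-KO had more genes against WT than double-KO with only the groups compared, array weights and centring, and among informative genes only with the first of these. Without 1 array, r of the Jmjd1a effect lay between 0.344 and 0.488, and that of the Jmjd1b effect changed sign, from -0.115 (without Jmjd1a-KO replicate 2) and -0.0543 (without double-KO replicate 2) to 0.142 (without double-KO replicate 1) and 0.182 (without Jmjd1a-KO replicate 1). Over the 139 named gene results, 1804 alternative values kept their side of the threshold and 666 lost it, and over the 38 list calls 604 kept it and 143 lost it. All 38 list calls were lost with an estimated correlation (0 left), while the other settings gave 26 to 50, with 37 when the deleted genes were left out of the lists. The estimated correlation also brings p-values from only 4 residual degrees of freedom. Its loss of calls therefore does not show that correlation between genes explains them. With only the groups compared, 86 named gene results lost their call and 39 kept their side of the threshold. With the replicate block these were 76 and 63. With the mean of all probe sets, 47 of the 139 named changes were smaller than the change given by more than 1.5 times, and 7 calls were lost. Flat probe sets in that mean draw a change toward 0 by construction. Depth over background could not be examined, since the table holds 1 value per probe set. The largest shift of the median of all genes by quantile normalization was 0.0075. Where a count moved, the cause was not tested, except that a stricter threshold lowers it by construction. An array left alone in its group was assumed to vary like the other groups.

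For Jmjd1a-KO against WT, the planned 374 genes were 645 with every probe set, 226 with quantile normalization, 237 with centring, 25 with only the groups compared, 13 with the replicate block, 227 with array weights, 61 at a log2 change of at least 1, 186 at an adjusted p under 0.01, 203 without flat genes and 1301 among informative genes. They ranged without 1 array from 16 (without WT replicate 2; 17 without WT replicate 1) to 982 (without Jmjd1a-KO replicate 2). The 1301 informative genes were 321 with only the groups compared, 866 with array weights and 206 at a log2 change of at least 1. With 1 array left out, these ranged from 139 (WT replicate 2) to 2335 (Jmjd1a-KO replicate 2), with 209 without WT replicate 1, 702 without Jmjd1a-KO replicate 1 and 591 without either Jmjd1b-KO array.

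For Jmjd1b-KO against WT, the planned 425 were 691 with every probe set, 14138 with centring (11645 flat), 1146 with only the groups compared, 16 with the replicate block, 2661 with array weights, 70 at a log2 change of at least 1, 4 at an adjusted p under 0.01, 255 without flat genes and 1708 among informative genes. Without 1 array they ranged from 6 (WT replicate 1) to 697 (either Jmjd1a-KO array), with 9 without WT replicate 2 or Jmjd1b-KO replicate 1 and 11 without Jmjd1b-KO replicate 2. The 1708 informative genes were 3335 with only the groups compared, 3582 with array weights and 259 at a log2 change of at least 1. Leaving out 1 array gave a range from 94 (WT replicate 1) to 2434, with 429 without WT replicate 2, 159 without Jmjd1b-KO replicate 1 and 150 without Jmjd1b-KO replicate 2.

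For double-KO against WT, the planned 2316 were 4676 with quantile normalization, 131 with only the groups compared, 1317 with the replicate block, 619 at a log2 change of at least 1, 525 at an adjusted p under 0.01 and 3477 among informative genes. Omission of 1 array gave 753 (WT replicate 1) to 2483, with 836 without WT replicate 2, 986 without either Jmjd1b-KO array, 1120 without double-KO replicate 1 and 1310 without double-KO replicate 2. The 3477 informative genes were 777 at a log2 change of at least 1 and ranged from 2121 (WT replicate 2; 2134 for WT replicate 1) to 3908 without 1 array.

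For double-KO against Jmjd1a-KO, the planned 816 were 1256 with quantile normalization, 18 with only the groups compared, 380 with the replicate block, 391 with the replicate block and crossed double-KO numbers, 268 with array weights, 198 at a log2 change of at least 1, 236 at an adjusted p under 0.01 and 2155 among informative genes. Without 1 array they ranged from 421 (either Jmjd1b-KO array; 487 for either WT array) to 952. The 2155 informative genes were 401 with only the groups compared, 1079 with array weights and 372 at a log2 change of at least 1, and ranged from 1244 (double-KO replicate 1) to 2219 without 1 array.

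For double-KO against Jmjd1b-KO, the planned 2629 were 12725 with quantile normalization (9086 flat), 15466 with centring (11642 flat), 1347 with only the groups compared, 1522 with the replicate block, 710 at a log2 change of at least 1 and 645 at an adjusted p under 0.01. Without 1 array they ranged from 720 (Jmjd1b-KO replicate 2) to 2654, with 802 without Jmjd1b-KO replicate 1, 1425 without either WT array, 1152 without double-KO replicate 1 and 1688 without double-KO replicate 2. Among informative genes 3721 passed, 869 at a log2 change of at least 1, with 2196 (Jmjd1b-KO replicate 2; 2317 for replicate 1) to 4224 without 1 array.

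For the interaction, the planned 696 were 339 with the mean of probe sets, 1085 with every probe set, 14235 with centring (11643 flat), 34 with the replicate block, 193 at a log2 change of at least 1, 49 at an adjusted p under 0.01, 435 without flat genes and 1894 among informative genes. Without 1 array they ranged from 19 (Jmjd1b-KO replicate 1) to 1168 (Jmjd1a-KO replicate 2), with 137 and 41 without WT replicates 1 and 2, 39 without Jmjd1b-KO replicate 2 and 183 without double-KO replicate 1. The 1894 informative genes were 655 at a log2 change of at least 1 and ranged from 629 (Jmjd1b-KO replicate 2) to 2562 without 1 array, with 839 and 834 without WT replicates 1 and 2, 722 without Jmjd1b-KO replicate 1 and 1186 without double-KO replicate 1.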

Other observations

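The test of an imprinting state in this part was chosen only after the result was seen, while those of a failing probe set and of whole chromosomes were set before. Imprinted genes went both ways in double-KO against WT. The 6 that rose were Sgce (1.61), Ndn (1.23), Peg3 (1.23), Mkrn3 (1.11), Impact (0.98) and Snrpn (0.78), which are known as genes expressed from the paternal copy. The 5 that fell were Rian (-6.52), Grb10 (-5.75), Phlda2 (-5.05), Meg3 (-5.01) and Cdkn1c (-3.95), which are known to be expressed from the maternal copy in most tissues. Nap1l5, also paternal, had a change of -0.73, not past the threshold. The fit of informative genes called 9 imprinted genes higher and 7 lower, and the further ones were not grouped by copy. Impact and Peg3 also rose, and Rian, Meg3 and Cdkn1c also fell, in Jmjd1a-KO against WT. This grouping by parental copy was made after the values were seen, and no test of allelic expression was possible with these arrays.

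The single losses called 10 measured genes in opposite directions in the planned fit and 132 among informative genes. Hormad1 fell by 1.40 in Jmjd1a-KO and rose by 1.90 in Jmjd1b-KO. The latter call was lost without WT replicates 1 (1.87) and 2 (1.94) and Jmjd1b-KO replicates 1 (2.00) and 2 (1.80). The former was not checked with arrays left out. Dnmt3l, a cofactor of DNA methylation, had changes of -1.56 and 1.87, and neither passed over all genes. Klf2, a naive pluripotency factor, rose by 1.08 in Jmjd1b-KO and by 1.97 in double-KO.

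Meg3 and Rian were lower in both groups without Jmjd1a. A failing probe set is argued against, since 7 of 12 other informative probe sets of these genes fell by at least 1 on the log2 scale in both groups, though 5 of Meg3 did not. An imprinting state fixed in the line from which both groups derive remains a candidate explanation: the larger difference between double-KO and Jmjd1a-KO was 0.19, which loss of Jmjd1a predicts too, so the 2 cannot be told apart with 1 line of origin. The planned call of Meg3 in Jmjd1a-KO against WT (adjusted p = 0.0497) was lost with any 1 of the 8 arrays left out (changes of -5.74 to -4.15), that in double-KO against WT without either Jmjd1b-KO array (-5.01) and without double-KO replicates 1 (-5.08) and 2 (-4.95), and that of Rian in Jmjd1a-KO against WT without WT replicates 1 (-6.20) and 2 (-7.22).

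Gain or loss of a whole chromosome in a line may shift many genes at once. It was tested with the median change of the informative genes of each chromosome against the rest, for the autosomes and X. The assembly GRCm38.p6 placed 7168 of 7181 genes on these, and the Y chromosome was left out. The largest value was -0.21, for chromosome 1 in Jmjd1b-KO against WT, with -0.20 and -0.24 for replicates 1 and 2. Chromosome 19 had -0.18, -0.15 and -0.20 in Jmjd1a-KO, Jmjd1b-KO and double-KO against WT, comparisons that share the WT arrays. Chromosome 1 also had -0.15 in Jmjd1a-KO and -0.13 in double-KO against WT. Chromosome 11 had 0.142 in Jmjd1b-KO against WT (0.139 for each replicate). The X chromosome had 0.20 in double-KO against Jmjd1b-KO (0.25 and 0.17 for replicates 1 and 2) and 0.13 against WT. These values over both arrays lie between the limit of 0.1 set for no change and that of 0.25 set for a gain or loss, so copy number stays open. In double-KO, chromosomes 1 and 19 had 0.01 and -0.02 against Jmjd1a-KO and 0.05 and -0.05 against Jmjd1b-KO. Their shift thus mainly sets WT apart from the KO groups, and whether it lies in WT was not tested.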
